A study of Mus musculus with 4 samples.

How the data were processed

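Ovaries of Tex14 +/- and Tex14 -/- mouse embryos at embryonic day 13.5 were profiled by droplet single-cell RNA sequencing with a 3' tag kit (10x Chromium, v2 chemistry, per the labels' protocols). There were 4 deposited tables from 2 libraries, each library in a shallow and a deep sequencing run, and the groups were taken from the genotype label of each sample. The Tex14 +/- library pooled 3 ovaries and the Tex14 -/- library 2, per the series' design text. Both runs of a library come from the same cells, so the shallow run was treated as a technical repeat and each genotype as 1 sample.

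The deposited tables hold whole-number UMI counts per gene and cell barcode, made by the authors and not normalized. Per the submitters' processing notes, Cell Ranger 2.1.0, Seurat 3.1 and the mouse genome build mm10 were used; their roles, the aligner, the gene annotation and the cell filters are not given in the sources used here. The counts themselves show that barcodes had been filtered before deposit. In the deep run no barcode exceeded 5.00% mitochondrial UMIs or 29982 UMIs, and none had fewer than 1001 genes. In the shallow run no barcode exceeded 7.00% mitochondrial UMIs or 24988 UMIs. The deep tables list 31053 genes for each library, while the shallow tables list 18964 genes (Tex14 +/-) and 19256 genes (Tex14 -/-). Cells of very high or low counts are therefore not represented.

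The submitters state 55744 (Tex14 +/-) and 41117 (Tex14 -/-) mean reads per cell for the deep run and 23567 and 19735 for the shallow run. The deep tables held 11794 and 13982 barcodes with 165333131 and 177851392 UMIs, and those of the shallow run held 12260 and 14715 barcodes with 106943156 and 113220425 UMIs. Ribosomal protein genes took 27.5% and 25.0% of UMIs in the deep run. Tex14 +/- cells were deeper, with a median of 13533 UMIs against 12145 UMIs, so shares of cells with a UMI were compared only after thinning.

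A minimum of 1000 UMIs and 500 genes per barcode removed no barcode. Doublets were called in each library with Scrublet as held in scanpy 1.11.5 (expected rate 8%), which called 821 (6.96%) Tex14 +/- and 1338 (9.57%) Tex14 -/- barcodes of the deep run; called doublets and the remaining cells of clusters with more than 50% called doublets were removed, leaving 10821 and 12608 cells. Cells of both libraries were clustered together, on 2000 variable genes and 30 principal components of log-normalized counts, with a shared-neighbour graph over 15 neighbours and the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9, resolution 1, alternatives 0.5 and 2), without batch correction. Clusters were named from markers of 12 cell types. A marker was positive when found in at least 20% of the cells of a cluster at 3 or more times the lower quartile of all clusters; a name needed at least 3 positive markers and more than 50% of its list. Types within 10 percentage points of the best were ranked by their markers among the 10 leading genes, and a cluster with more leading markers of another type stayed unnamed. This naming rule was revised after the clusters were seen. Clusters left unnamed held 11.5% of Tex14 +/- and 11.6% of Tex14 -/- cells; they resembled stroma or pregranulosa cells but their leading genes included markers of other types. Clusters 0, 1 and 3 held more than 50% of germ cells in both libraries. Germ cell clusters 5 (5.7% of Tex14 +/- and 8.5% of Tex14 -/- cells kept), 8 (3.9% and 7.5%) and 14 (0.70% and 3.0%) were larger in the Tex14 -/- library. Clusters 0 (14.4% and 12.4%), 1 (13.6% and 12.2%), 3 (13.1% and 10.8%) and 4 (8.7% and 8.2%) were smaller. The clusters were formed on the same counts, so these sizes are not independent of the gene ratios. Classes under 100 cells in either library were not compared, which left germ cells, pregranulosa-like, surface epithelium-like and interstitial stroma-like cells.

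UMIs were summed over the cells of a class and library and scaled to 1000000 UMIs per class (CPM), with exact Poisson intervals. Log2 ratios are Tex14 -/- over Tex14 +/-, without a pseudocount, and carry exact conditional binomial intervals. Ranks, the 2-fold counts, the median over all genes and the median members of lists with their percentiles used log2 ratios of CPM plus 5. A list was summed over members with 5 CPM or more in at least 1 genotype of the class, so the genes summed could differ between classes. Its median member was placed among 10000 random lists of equal size drawn from the 50 genes nearest in mean expression to each member. A member counted as higher or lower at 1.5-fold or more. The 18 lists covered pluripotency, primordial germ cell specification, germline genes and genome defence, meiotic initiation, meiotic prophase, retinoic acid, BMP and WNT response, intercellular bridge and abscission, oocyte growth and follicle assembly, male germ cell genes, S phase, G2 and M phase, p53 response, immediate early and heat shock genes, glycolysis, mitochondrially encoded genes and Y-linked genes, besides the marker lists of the 12 cell types (germ cell, pregranulosa, surface epithelium, interstitial stroma, endothelium, perivascular, immune, erythroid, mesonephric epithelium, neural, steroidogenic and Sertoli). The result of the neural list is not reported here. Gene coordinates came from the GENCODE M21 annotation of GRCm38, in which 30464 of 31053 symbols matched.

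Genes were named by a rule fixed, like the lists, the markers and the design, before the data were examined. In germ cells these were the 12 highest and 12 lowest ratios among genes with 50 CPM or more in at least 1 genotype whose shallow-run ratio had the same sign, and in each somatic class the 5 highest and 5 lowest. From each list up to 4 members with 20 CPM or more and the largest absolute ratio were named, and Tex14, Dazl, Stra8, Sycp3, Rec8, Pou5f1, Nanog, Sox2 and Ddx4 always. Members named beyond this rule (Lin28a, Lin28b, Tfcp2l1, Phc1, Utf1, Klf5, Tfap2c, Aurkb, Sp5, Znrf3, Ooep, Gm47283, Mki67, Lhx2, Acta2, Pecam1, Egfl7, Wnt4 and Gata2 in stroma-like cells and those of the shares of cells) were chosen after their values were seen.

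For shares of cells, each germ or pregranulosa-like cell was thinned at random to 3000 UMIs, which left out 35 Tex14 +/- and 25 Tex14 -/- germ cells as shallower. Shares carry Clopper-Pearson intervals, and differences of shares carry Newcombe intervals. Free RNA in droplets was gauged by the same share in pregranulosa-like cells. The 5 bins of meiotic level, the Fano factors and Spearman's rho used the same thinned germ cells. No statistical test was made and no p-value is given, because cells are not replicates.

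Alternatives were another sequencing run, scaling by the median of gene ratios, a mean over cells of per-cell CPM, a minimum of 2000 UMIs, doublets kept, germ cells defined by 3 or more detected markers without clustering, totals without ribosomal and mitochondrial genes, other expression minima and pseudocounts, other thinning depths and seeds, 3 bins and other clustering resolutions. Added after the data were seen were the pluripotency list and the bins without Pou5f1, bins at 6000 UMIs per cell, unthinned bins on shares of UMIs, 3 lists (pluripotency, meiotic prophase, G2 and M phase) without clusters 8 and 14, and the 2-fold count without haemoglobin genes.

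The ratio and list calculations were tested on simulated counts drawn from the germ cell levels of these libraries (8949 genes, 200 of them altered). Intervals of the 8749 unaltered genes covered the true ratio in 94.8%. Genes raised or lowered 2-fold (63) and 4-fold (69) had median absolute log2 ratios of 1.00 and 1.99, and 100% of both lay past 1.5-fold; of 68 genes altered by exactly 1.5-fold, 51.5% did. Among 100 unaltered lists of 19 genes the median percentile was 46.5 and 5 lay outside 2.5 to 97.5. A list whose computed log2 ratios were each raised by a factor of 1.4 after the draw reached percentile 100, a place set by that step. The simulated counts held Poisson noise alone, so spread between cells or libraries was not covered. Thinned shares with Pou5f1 of 11.6% and 20.0% were expected from the full counts, and 11.9% and 20.3% were drawn. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures matplotlib 3.10.9. Endothelium-like cells (89 and 87), immune-like cells (25 and 30) and mesonephric epithelium-like cells were left out of comparisons for their low numbers.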

Results

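Single-cell transcriptomes of mouse ovaries at embryonic day 13.5 were compared between Tex14 +/- and Tex14 -/- embryos. TEX14 is a component of the intercellular bridges that keep sister germ cells joined after incomplete cytokinesis, and the title of the series asks how these bridges bear on the exit of fetal oocytes from pluripotency and their entry into meiosis. Germ cells had been sorted on an Oct4-GFP reporter and mixed back with GFP-negative somatic cells, and 1 droplet library was made per genotype, from 3 pooled Tex14 +/- ovaries and 2 pooled Tex14 -/- ovaries of mixed strain. Each library was sequenced in a shallow and a deep run. The deep run held 165333131 UMIs (unique molecular identifiers, 1 per captured transcript) in 11794 Tex14 +/- barcodes and 177851392 UMIs in 13982 Tex14 -/- barcodes, with medians of 13533 and 12145 UMIs per barcode. With 1 library per genotype there were no biological replicates and no test was made. All intervals are 95% intervals for counting error alone, so each difference is one between these 2 libraries.

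Tex14 itself was lower in germ cells of the Tex14 -/- library, at 54.3 CPM (UMIs of a gene per 1000000 UMIs of the class) against 88.7 CPM in the Tex14 +/- library, a log2 ratio of −0.71 (−0.76 to −0.66) or 1.63-fold lower. After every cell was thinned to 3000 UMIs, 15.4% of Tex14 -/- germ cells and 22.4% of Tex14 +/- germ cells held a Tex14 UMI, against 0.965% and 0.872% of pregranulosa-like cells in the same libraries. In the shallow run the log2 ratio was −0.91. Tex14 lies on chromosome 11 at 87405065 to 87555823 (GRCm38). The labels do not state which part of the gene is deleted, and 3' tags outside that part would persist, so this value does not check the genotype.

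Germ cell-like cells, which expressed Dazl, Ddx4, Mael and Taf7l, made up 60.1% (59.2 to 61.0) of 10821 Tex14 +/- cells and 62.5% (61.7 to 63.4) of 12608 Tex14 -/- cells. Pregranulosa-like cells, the Foxl2 and Fst expressing supporting cells of the ovary, made up 15.97% (15.3 to 16.7) and 13.2% (12.6 to 13.8). Surface epithelium-like cells made up 6.81% and 7.07%, and interstitial stroma-like cells made up 4.56% and 4.59%. The surface epithelium-like class was cluster 7, in which 66.7% of surface epithelium and 71.4% of pregranulosa markers were positive. Its name rested on the leading genes Upk3b, Krt19 and Krt7, so its markers overlap those of pregranulosa-like cells. Endothelium-like and immune-like cells stayed under 1% in both libraries, and 14 mesonephric epithelium-like cells were found in the Tex14 -/- library only. Because germ and somatic cells had been sorted and recombined, these shares describe the loaded mixtures and not the ovaries.

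Transcripts of pluripotency genes were higher in Tex14 -/- germ cells. The 19 measured genes of the pluripotency list together reached 1302 CPM in Tex14 -/- against 931 CPM in Tex14 +/- germ cells, a log2 ratio of 0.48 (0.47 to 0.49). Pou5f1, the core pluripotency factor better known as Oct4, was at 94.3 against 51.0 CPM (0.89, 0.84 to 0.94), and its partner Sox2 was at 30.3 against 17.6 CPM (0.78, 0.70 to 0.87). Klf5 (0.67), the germ cell and naive pluripotency marker Dppa3 (255 against 170.0 CPM, 0.58), Dppa5a (568 against 385 CPM, 0.56) and Utf1 (0.40) were higher as well. In all, 5 of the 19 members were at least 1.5-fold higher, none was 1.5-fold lower, and Lin28a, Lin28b, Tfcp2l1 and Phc1 had ratios below 0, at −0.13, −0.21, −0.20 and −0.19. With 5 CPM added, as for all list medians, the median member had a log2 ratio of 0.28. It lay at percentile 100 of 10000 random lists matched on expression. The G2 and M phase, immediate early and erythroid marker lists shared that place, and the primordial germ cell (99.8), WNT (99.8) and S phase (99.7) lists lay close by. The list ratio was 0.35 without clusters 8 and 14, as described for the meiotic genes below. Nanog, another core pluripotency factor, was too low to compare by level. Pou5f1 also drives the reporter used for the sort, so an effect of the sorting gate was not ruled out, and the haemoglobin transcripts of red blood cells were higher in the same cells (log2 ratio 1.79).

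The genes of early meiosis differed less and in both directions. Meiotic initiation genes summed to 2176 CPM in Tex14 -/- against 2433 CPM in Tex14 +/- germ cells, a log2 ratio of −0.16 (−0.17 to −0.15), which followed Stra8, the retinoic acid induced gatekeeper of meiosis (1553 against 1822 CPM, −0.23). Rec8, the meiotic cohesin, stood at 188 CPM in both (−0.00, −0.03 to 0.03), and Meioc (0.06), Gm4969, also known as Meiosin (0.05), and Ythdc2 (−0.02) lay close to 0, so that the median member was at −0.00 and percentile 18.1. Meiotic prophase genes, which build the synaptonemal complex and repair programmed DNA breaks, summed to 10826 against 11693 CPM (log2 ratio −0.11), with the median member at −0.03 and near the lowest of the random lists (percentile 0.10). None of its 38 measured members and none of the 5 meiotic initiation members passed 1.5-fold. The meiotic cohesin subunit Smc1b (1793 against 2372 CPM, −0.40) and the synaptonemal complex gene Syce3 (376 against 459.8 CPM, −0.29) were lower, while Meiob (122 against 97.9 CPM, 0.32) and Tex11 (0.25) were higher. Smc1b alone made up most of the difference of the prophase sum, while 22 members were below 0 and 16 above 0. Sycp3 had a ratio of 0.05, which turned to −0.03 and −0.01 under the other scalings. The prophase ratio was −0.015 when clusters 8 and 14, the germ cell clusters whose shares differed by the largest factors between the libraries, were left out, a choice made after the data were seen. It was −0.19 when scaled by the median of gene ratios and −0.18 when ribosomal and mitochondrial genes were left out of the totals.

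**Figure D1:**
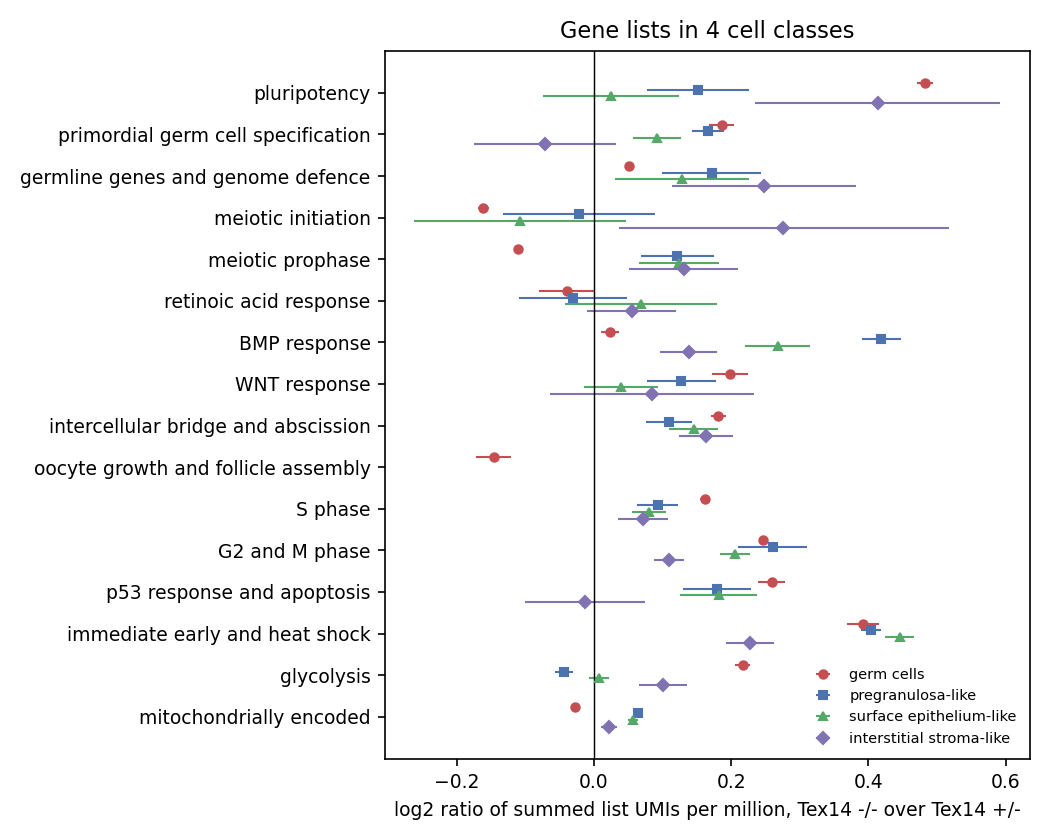
Log2 ratio of summed CPM, Tex14 -/- over Tex14 +/-, for each gene list (vertical axis) in germ cells and 3 somatic classes, with 95% intervals for counting error. Pluripotency genes in germ cells sit at 0.48, while meiotic initiation and prophase genes sit at −0.16 and −0.11, led by Stra8 and Smc1b. The small ratios of 0.05 (germline genes) and 0.02 (BMP response) in germ cells turned below 0 under other scalings. List members were kept by their level in each class, so the genes summed can differ between classes.

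Germline genes were close to level, while genes of primordial germ cell specification were higher. The list of germline and genome defence genes, which hold the germ cell programme and silence transposons, had a log2 ratio of 0.05 that turned to −0.03 and −0.01 under the other scalings, and 0 of its 18 members passed 1.5-fold. Within it, Tex19.1 (0.28), Slc25a31 (0.22), Ddx4 (232 against 204 CPM, 0.19) and the RNA-binding protein gene Dazl (1865 against 1699 CPM, 0.13) were higher, and Taf7l (−0.22) was lower. Scaling by the median of gene ratios brought Ddx4 to 0.11 and Dazl to 0.05. Of 6 measured genes of primordial germ cell specification, 2 were at least 1.5-fold higher, Dnd1 (32.2 against 19.5 CPM, 0.73) and the low Tfap2c. The list had a log2 ratio of 0.19, which fell to 0.10 by the median of gene ratios and 0.12 without ribosomal and mitochondrial genes. Alpl (0.33), Ifitm3 (0.26) and Ifitm1 (0.07) were the other members above the level for examples. Of the oocyte growth list, only Figla, Sohlh2 and Ooep were measured. Figla, which later directs zona pellucida and follicle genes, was at 129.9 against 167 CPM (−0.36) and Sohlh2 was higher (0.21). The sum (−0.15) and the median (0.19 with 5 CPM added) of this list had opposite signs. Male germ cell genes and Y-linked genes stayed under 5 CPM in both libraries.

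Most cell division genes had ratios above 0 in Tex14 -/- germ cells, few of them by 1.5-fold, while the median over all genes at 50 CPM or more was itself 0.08 with 5 CPM added. The G2 and M phase list had a log2 ratio of 0.25 (0.24 to 0.25) with 27 of its 28 members above 0 and 4 at least 1.5-fold higher. Cyclin B1 (Ccnb1), which drives entry into mitosis, was at 59.2 against 27.5 CPM (1.11), Aurka at 22.4 against 13.2 CPM (0.76), Nusap1 at 40.7 against 24.7 CPM (0.72) and Ccnb2 at 138 against 89.6 CPM (0.63). The exception was the proliferation marker Mki67 (67.1 against 73.4 CPM, −0.13), found in 17.7% of Tex14 -/- and 19.6% of Tex14 +/- thinned germ cells. S phase genes had a log2 ratio of 0.16 with 0 of 23 members past 1.5-fold (Slbp 0.39, Rrm2 0.36, Mcm6 0.36, Mcm2 0.34). In the list of bridge and abscission genes (0.18), Plk1 (0.83) and the low Aurkb were at least 1.5-fold higher and Tex14 was 1.5-fold lower, among 17 measured; Kif20a (0.55) and Prc1 (0.45), which act in the central spindle during cytokinesis, were also higher. The G2 and M phase list was higher in pregranulosa-like (0.26), surface epithelium-like (0.21) and stroma-like (0.11) cells too, so a ratio above 0 was not limited to germ cells. Its sums were 417 against 348 CPM in pregranulosa-like cells, where 17 of 28 members were measured, and 5338 against 4502 CPM in germ cells. Surface epithelium-like cells held 3355 against 2910 CPM and stroma-like cells 7101 against 6581 CPM. Germ cell markers were also higher in these somatic classes, and carried-over germ cell RNA was not tested as a source of these ratios. In germ cells the G2 and M phase ratio was 0.19 without clusters 8 and 14. Their leading genes include Ccnb1 or Pou5f1, and they held a larger share of Tex14 -/- germ cells. Scaled by the median of gene ratios, the G2 and M phase, S phase and bridge lists in germ cells were at 0.16, 0.08 and 0.10.

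Other lists in germ cells were compared with the same lists in the soma where they differed. The median gene at 50 CPM or more, with 5 CPM added, was at 0.08 in germ cells and 0.04 in each somatic class. Scaling by the median of gene ratios thus lowered germ cell ratios most. So scaled, the immediate early, glycolysis and WNT lists in germ cells were at 0.31, 0.13 and 0.12. Immediate early genes, the fast response to stimulation and to tissue dissociation, had a log2 ratio of 0.39. Of 9 members measured in germ cells, 2 were at least 1.5-fold higher, and Jund (0.57), Ier2 (0.49) and Fos (0.46) were above 0. The list stood at 0.40, 0.45 and 0.23 in pregranulosa-like, surface epithelium-like and stroma-like cells, where 18, 18 and 17 members were measured. p53 response genes had a ratio of 0.26 with 0 of 12 members past 1.5-fold (Mdm2 0.40, Ccng1 0.39, Bax 0.35, Cdkn1a 0.23), against 0.18, 0.18 and −0.01 in the same somatic classes. Scaled by the median of gene ratios, the p53 list was at 0.18 in germ cells against 0.15, 0.15 and −0.05. Glycolysis genes had a ratio of 0.22, with Eno1 (40.1 against 22.8 CPM, 0.82) at least 1.5-fold higher of 14, followed by Pgam1 (0.43), Aldoa (0.42) and Pkm (0.36), against −0.04 in pregranulosa-like, 0.10 in stroma-like and 0.01 in surface epithelium-like cells, the last turning below 0 under the other scalings. WNT response genes had a ratio of 0.20, with Sp5 at least 1.5-fold higher of 8 and Lef1, a nuclear effector of the pathway, at 0.57; Tcf7 (0.36) and Nkd1 (0.22) followed, and Znrf3 was below 0. BMP response genes were at 0.02, a value that turned below 0 under the other scalings, with Gata2 (0.37), Id2 (0.22), Msx1 (0.18) and Msx2 (0.12) above 0. In all, 7 of the 8 BMP members were above 0 and 1 below, and the median member was at 0.14 with 5 CPM added. Retinoic acid response genes were at −0.04 (−0.08 to 0.00) with 0 of 3 members past 1.5-fold (Crabp1 −0.00, Crabp2 −0.04). Mitochondrially encoded genes were at −0.03, with mt-Nd3 1.5-fold lower (−0.60) of 13 and mt-Nd2 (−0.36), mt-Atp8 (−0.35) and mt-Nd4l (0.30) next.

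Among single genes named by size, 8 of 3207 germ cell genes at 50 CPM or more differed by 2-fold or more on the log2 scale with 5 CPM added, 5 higher and 3 lower in Tex14 -/-, around a median of 0.08 over all of these genes. Ccnb1, at 1.11 without and 0.98 with the added 5 CPM, is not among the 5, and the lower genes are H2-Ab1, Sfi1 and the gene model Gm47283 (−1.13), which is absent from the shallow tables and so outside the rule for named genes. The haemoglobin genes Hba-a1 (204 against 47.8 CPM, 2.09), Hbb-bs (1.84), Hbb-bt (1.34) and Hba-a2 (1.24) and the gene model Gm10260 (1.53) had the highest ratios, followed by Ccnb1, the histone gene Hist1h2ap (196 against 104 CPM, 0.92), Pou5f1, the methylglyoxal detoxifying enzyme Glo1 (274 against 161 CPM, 0.77), Rp9 (0.77) and the imprinted growth regulator Phlda2 (136 against 85.5 CPM, 0.67); the gene model Gm10076 (0.84) was also higher. The lowest ratio was that of H2-Ab1, an MHC class II chain (16.3 against 75.9 CPM, −2.22, 4.65-fold lower). Sfi1 (−1.25), the X-linked germ cell genes Xlr5a (−1.03), Rhox13 (96.9 against 185 CPM, −0.94) and Trap1a (147 against 232 CPM, −0.66), Phpt1 (−0.86), Rnaset2a (−0.78), the lactate dehydrogenase subunit gene Ldhb (106 against 177 CPM, −0.74), Tex14, Rpl27 (−0.66), Rpl36al (−0.61) and Gm10036 (−0.67) were lower. Reads of the haemoglobin, histone, Xlr, Sfi1, Rnaset2a, ribosomal protein and Gm genes can be split between near-identical copies, so their levels are uncertain. On the same scale the 2-fold count was 5 in the shallow run and 4 (1 higher, 3 lower) without the haemoglobin genes.

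Cells holding pluripotency transcripts were more frequent among Tex14 -/- germ cells at equal depth. With 3000 UMIs per cell, a Pou5f1 UMI was found in 20.3% (19.4 to 21.2) of 7860 Tex14 -/- and 11.9% (11.2 to 12.7) of 6469 Tex14 +/- germ cells, a difference of 8.32 percentage points (7.13 to 9.51). Dppa3 was found in 34.7% and 25.8%, Sox2 in 6.84% and 4.16%, Utf1 in 13.8% and 11.5%, and Zfp42 in 8.02% and 6.74%. Nanog was found in 0.331% and 0.108%, near its share in pregranulosa-like cells (0.181% and 0.058%), and no difference is read from it. Pregranulosa-like cells, which should lack Pou5f1, held it in 1.15% and 0.640%, and Dppa3 in 1.39% and 1.45%, at median depths of 8636 and 10960.5 UMIs against 13401 and 15149 UMIs in germ cells before thinning. Unthinned, the Pou5f1 shares were 51.4% and 38.5%.

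Most germ cells of both genotypes held meiotic transcripts. Stra8 was found in 89.8% (89.1 to 90.4) of Tex14 -/- and 90.8% (90.1 to 91.5) of Tex14 +/- thinned germ cells, a difference of −1.02 points (−1.99 to −0.04), against 7.78% and 9.07% of pregranulosa-like cells; another random draw gave −0.49 (−1.47 to 0.50), 1500 UMIs per cell gave −3.10 (−4.41 to −1.78) and unthinned cells, nearly all of which held Stra8, gave 0.40 points (−0.13 to 0.94). No size is read from this share, while Stra8 by CPM was lower in every alternative (−0.31 to −0.18). Sycp1, which forms the transverse filaments of the synaptonemal complex, was found in 70.7% against 76.1% of cells, Syce3 in 58.2% against 63.2%, the recombination hotspot methyltransferase Prdm9 in 36.6% against 41.4%, the recombinase Dmc1 in 25.1% against 28.5% and Figla in 31.6%, 6.44 points less than in Tex14 +/-. Rec8 was found in 33.5% and 32.1%, Dazl in 99.3% of Tex14 -/- cells and 0.295 points less of Tex14 +/- cells, and Ddx4 in 49.6% and 45.3%. The share with Sycp3 (90.6% and 92.5%) ran against its CPM, and no order is read from it.

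**Figure D2:**
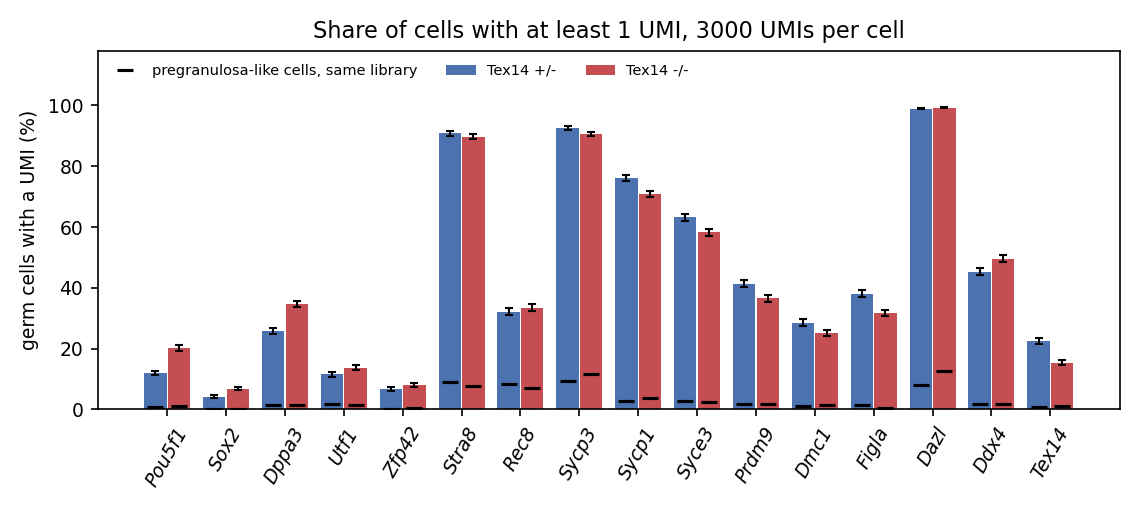
Share of germ cells (vertical axis, percent) with at least 1 UMI of each gene after thinning to 3000 UMIs per cell, for Tex14 +/- and Tex14 -/- libraries, with 95% Clopper-Pearson intervals and, as black dashes, the share in pregranulosa-like cells of the same library. Pou5f1 was found in 20.3% of Tex14 -/- and 11.9% of Tex14 +/- germ cells, and Stra8 in 89.8% and 90.8%.

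The overlap of both programmes was larger in the Tex14 -/- library. Pou5f1 and Stra8 were found together in 18.6% (17.7 to 19.4) of Tex14 -/- and 11.3% (10.5 to 12.1) of Tex14 +/- germ cells, a difference of 7.26 points (6.10 to 8.41). If Pou5f1 and Stra8 fell on cells independently within each library, 18.2% and 10.8% would hold both, so that the overlap followed the Pou5f1 share. Pou5f1 with Sycp3 was found in 15.8% and 9.72%, less than the 18.3% and 11.04% of independence in both libraries, and Dppa3 with Sycp3 in 27.3% and 20.9%. The Pou5f1 and Stra8 difference depended on depth, at 3.15 points with 1500 UMIs per cell and 12.5 points without thinning.

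At a like level of meiotic transcripts, Tex14 -/- germ cells held more pluripotency transcripts. Germ cells thinned to 3000 UMIs were divided into 5 bins by their UMIs of the meiotic initiation and prophase lists together, with edges at the quintiles of the Tex14 +/- library. The lowest bin, with up to 30 meiotic UMIs, held 28.9% of Tex14 -/- and 21.5% of Tex14 +/- germ cells, and the highest bin held 14.9% and 18.6%. Pluripotency UMIs per cell were 6.60 against 5.16 in the lowest bin and 2.45 against 1.93 in the middle bin, and were higher in Tex14 -/- in each of the 5 bins, with log2 ratios of 0.36, 0.28, 0.35, 0.37 and 0.32. The mean over the bins was 0.33 (0.30 to 0.37), and 0.31 with Pou5f1 left out of the list, which was done after the data were seen. Without thinning, where Tex14 +/- germ cells were deeper, the mean was 0.12 on counts and 0.35 (0.33 to 0.36) when bins and levels were taken as shares of each cell's UMIs, an alternative added after the data were seen. Within each bin the mean meiotic UMIs were somewhat lower in Tex14 -/-, at 19.4 against 20.7 in the lowest, 45.9 against 46.1 in the middle and 67.8 against 68.5 in the highest. How much of the ratios this remaining mismatch makes up was not tested. A bin is a range of UMI counts and not a cell type.

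**Figure D3:**
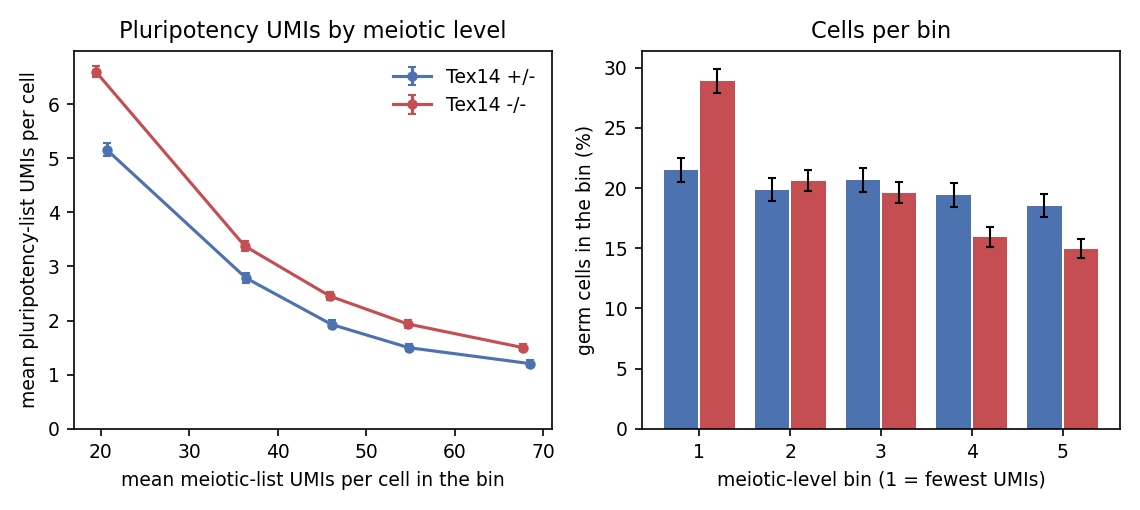
Left, mean pluripotency-list UMIs per germ cell against mean meiotic-list UMIs per cell in 5 bins of meiotic level (intervals, 95% Poisson); right, share of germ cells in each bin (percent, 95% Clopper-Pearson intervals), at 3000 UMIs per cell. Tex14 -/- lies above Tex14 +/- in each bin, with 6.60 against 5.16 pluripotency UMIs per cell in the lowest and 2.45 against 1.93 in the middle.

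Germ cells of the Tex14 -/- library were more spread in their meiotic UMIs. The variance over the mean (Fano factor) of meiotic UMIs per thinned cell was 7.54 in Tex14 -/- and 6.47 in Tex14 +/- germ cells, at means of 40.9 and 44.6 UMIs. That of pluripotency UMIs was 2.99 and 2.30, but their mean differed in the same direction (3.62 and 2.58 UMIs) and the factor tends to grow with the mean, so no wider spread is read from it. Spearman's rho between meiotic and pluripotency UMIs across cells was −0.62 in Tex14 -/- and −0.57 in Tex14 +/- germ cells, a value across cells of 1 library, which are not replicates. The difference of rho was −0.05 at this depth and −0.13 without thinning. The ratio of the meiotic Fano factors was 1.17 at this depth and 1.06 without thinning.

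Somatic cells were compared to see how the libraries differed outside the germ cells, where TEX14 bridges are not known. In pregranulosa-like cells the amino acid transporter gene Slc7a2 was at 3.28 against 59.1 CPM in Tex14 -/- and Tex14 +/- (log2 ratio −4.17, −4.62 to −3.75, 18.0-fold lower). Asparagine synthetase (Asns, 39.0 against 106 CPM, −1.44), Adck5 (−1.27), cytochrome b5 reductase (Cyb5r3, 187 against 430.1 CPM, −1.20) and the secreted protease gene Adamts19 (−0.85) were lower as well. In surface epithelium-like cells Ly6e (37.8 against 94.1 CPM, −1.32), Hist1h2bc (−0.88), Poldip3 (−0.86), Rnaset2a (−0.80) and Adamts19 (−0.72) were lower. In stroma-like cells Hoxa10 (15.1 against 54.9 CPM, −1.86), a patterning gene of the reproductive tract, the retinoic acid synthesis gene Aldh1a2 (18.4 against 52.0 CPM, −1.50), Tm4sf1 (−0.98), the growth factor gene Gas6 (−0.94) and the angiotensin receptor gene Agtr2 (71.6 against 136 CPM, −0.92) were lower. The 5 highest ratios per class were held by haemoglobin genes, Gm10260, Gm10076 and, in stroma-like cells, Hist1h2ap (1.15). By the same size rule, 11 of 3282, 9 of 3174 and 9 of 3337 genes in pregranulosa-like, surface epithelium-like and stroma-like cells differed by 2-fold or more.

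Marker and BMP response lists were compared within the soma. Pregranulosa markers in pregranulosa-like cells had a log2 ratio of 0.04, with 0 of 7 members past 1.5-fold, and surface epithelium markers in their own class were at −0.01 (−0.04 to 0.02). Interstitial stroma markers in stroma-like cells were at −0.12, with 8 of 9 below 0 and 0 past 1.5-fold. BMP response genes had summed ratios above 0 in pregranulosa-like (0.42) and surface epithelium-like (0.27) cells, with 0 of 7 members past 1.5-fold in either. In pregranulosa-like cells the BMP target genes Id1 (0.52), Id2 (0.26) and Id3 (0.46) made up most of the sum, and Smad6 (−0.22) was below 0. In stroma-like cells their sum (0.14) followed Id1, Id2 and Id3, while the other 3 measured members were below 0, Gata2 at −0.69 among them. The pluripotency list was low in the soma, at 184 against 166 CPM over 6 measured members in pregranulosa-like cells (log2 ratio 0.15). Klf2 (80.2 against 74.9 CPM) and Klf4 (69.8 against 60.2 CPM) made up most of that sum, so it does not show a pluripotency programme there. The list had ratios of 0.03 over 8 members in surface epithelium-like cells, which turned below 0 under the other scalings, and 0.41 (0.23 to 0.59) over 5 members in stroma-like cells. Erythroid markers, led by the haemoglobin genes, were higher by like amounts in germ (1.79), pregranulosa-like (1.75), surface epithelium-like (1.76) and stroma-like (1.64) cells.

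Markers of further cell types were checked for carry-over. Germ cell markers had a ratio of 0.11 in germ cells, a list that holds Pou5f1, Dppa5a and Dnd1. Mesonephric epithelium markers were at 0.19 in germ cells, led by Epcam (0.27), which germ cells also express. Endothelium markers were at 0.39 (0.29 to 0.50) in germ cells, from the low Pecam1 (0.85) and Egfl7 (0.06). That sum rested mainly on Pecam1, so no endothelial carry-over is read from it. Pregranulosa markers (−0.18, −0.28 to −0.08) and the surface epithelium marker Lhx2 (−0.09, −0.22 to 0.03) were below 0 in germ cells. Germ cell markers were higher outside the germ cells too, at 0.22 in pregranulosa-like, 0.20 in surface epithelium-like and 0.42 (0.26 to 0.58) in stroma-like cells. In stroma-like cells pregranulosa markers were at −0.43 (−0.59 to −0.27), with 3 of 7 members 1.5-fold lower and 1 higher, Wnt4 at −0.68 among them, and surface epithelium markers were at −1.50, from Aldh1a2 alone. In the same cells the perivascular list was at −0.08, the endothelium list at −0.11 (−0.31 to 0.09) and the Sertoli list, with 1 measured gene, at 0.49 (0.02 to 0.98). In pregranulosa-like cells the perivascular list, measured by Acta2 alone, was at 0.35 (0.11 to 0.59), surface epithelium markers at −0.19 and endothelium markers at −0.20 (−0.39 to −0.02), while steroidogenic markers were at −0.04 (−0.19 to 0.12) and Sertoli markers at 0.07 (−0.07 to 0.22). Immune markers stayed under 5 CPM in each of the 4 classes compared.

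The shallow run, a technical repeat of the same libraries, gave like values. It held 11600 of the deep Tex14 +/- barcodes (98.4%) and 13786 of the deep Tex14 -/- barcodes (98.6%), with deep cells holding 1.63 and 1.66 times as many UMIs. In its germ cells the pluripotency list had a log2 ratio of 0.47, Pou5f1 0.91, Dppa3 0.56, Sox2 0.76, Stra8 −0.23, Smc1b −0.40 and the meiotic prophase list −0.10. Rpl36al, named above for the deep run, had a ratio of −0.12 over the same germ cells in the shallow run, on the log2 scale with 5 CPM added, against −0.61 on that scale in the deep run.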

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

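The tests in this part were all chosen after the corneal transcripts had been seen; the Ly6e values carry no test.

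Krt12, a keratin specific to the corneal epithelium, had 9246 UMIs (81.7 CPM) in the shallow run of the Tex14 -/- library and 414 UMIs (3.87 CPM) in that of the Tex14 +/- library, although the tissue was ovary. The main values come from the deep run, while the shallow run serves as the repeat, in alternatives and for the sign that named genes had to keep. It came from few barcodes, as 72 Tex14 -/- barcodes with at least 10 Krt12 UMIs held 9155 of them and 5 Tex14 +/- barcodes held 327, and the deep run held 10 and 22 Krt12 UMIs in all.

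For the 12 of these barcodes found in both runs, cells of the pooled ovaries are argued against, since they held 595 Krt12 UMIs in the shallow run and 0 in the deep run, where 7 of them were germ cell-like. The other 65 barcodes are absent from the deep tables, so for them removal by the authors' filtering cannot be told apart from absence from the library. Of the 5 Tex14 +/- barcodes, 4 were also among the Tex14 -/- barcodes, as molecules of 1 outside library read on the same flow cell could give. That source stays open as a hypothesis, the other libraries of the flow cell being not analysed here, and no biological explanation was tested.

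Ly6e, a GPI-anchored surface protein gene, had opposite ratios in different classes. It was higher in Tex14 -/- germ cells (44.2 against 10.9 CPM, log2 ratio 2.02) and lower in Tex14 -/- surface epithelium-like cells (37.8 against 94.1 CPM, −1.32), with stroma-like cells at −0.87 and pregranulosa-like cells at 0.09. The difference between classes was not tested.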

How the results depend on the processing

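The alternatives without Pou5f1, without clusters 8 and 14, without haemoglobin genes, at 6000 UMIs per cell and on unthinned shares of UMIs were chosen after the results were seen. Of 150 alternative values, 99 stayed within the counting interval or tolerance of the main value, 48 moved and 3 changed sign where the main interval excluded 0; intervals cover counting error only, so with these depths small shifts pass them. The pluripotency ratio stayed above 0 in all 9 alternatives (0.35 to 0.49): 0.47 in the shallow run, 0.40 by the median of gene ratios, 0.42 without ribosomal and mitochondrial genes, 0.46 without Pou5f1 and 0.35 without clusters 8 and 14, whose leading genes include Dppa3, Dppa5a and Phlda2. The meiotic prophase ratio stayed below 0 in all 8 alternatives: −0.10 in the shallow run, −0.19 by the median of gene ratios, −0.12 as a mean over cells, −0.12 with doublets kept, −0.11 with germ cells defined by markers, −0.18 without ribosomal and mitochondrial genes and −0.015 without clusters 8 and 14. Under scaling to total UMIs most of it thus rested on the cells of those clusters. Their removal was not combined with the other scalings. Sycp3 turned to −0.032 by the median of gene ratios and −0.015 without ribosomal and mitochondrial genes, since these scalings shift all genes alike. The count of genes past 2-fold with 5 CPM added (8, of which 5 were higher) was 5 in the shallow run (3 higher), 4 without haemoglobin genes (1 higher) and 12 at a minimum of 20 CPM (6 higher). The Stra8 share difference (−1.02 points) was −3.10 at 1500 UMIs per cell and 0.40 without thinning. The share with both Pou5f1 and Stra8 differed by 3.15 points at 1500 UMIs per cell and by 12.5 without thinning. Without thinning, the ratio of the meiotic Fano factors was 1.06 against 1.17, the difference of rho −0.13 against −0.05, and the matched-bin ratio 0.12 against 0.33; the cause was not tested for the first pair, while unthinned bins on shares of UMIs gave 0.35, so counts at unequal depth made the last difference. In the other 8 alternatives the matched-bin ratio lay between 0.31 and 0.36. The germ cell share was 60.7% for Tex14 -/- in the shallow run, and 63.1% and 65.6% for Tex14 +/- and Tex14 -/- with germ cells defined by markers; the cause was not tested. Of 70 single-gene values, 44 stayed, 24 moved and 2, both of Sycp3, changed sign; Rec8, whose main interval includes 0, lay on both sides of it (−0.08 to 0.06). No paired analysis was possible because each genotype was 1 library. Nanog, the male germ cell genes and the Y-linked genes were too low to compare.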

Other observations

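The tests in this part were chosen after the results were seen, as were the bins at 6000 UMIs per cell in the test of counting noise, for which only the bound was written before that value was computed.

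Ldhb, a lactate dehydrogenase subunit gene, was lower in Tex14 -/- germ cells (−0.74) but higher in pregranulosa-like (1754 against 1206 CPM, 0.54), surface epithelium-like (0.39) and stroma-like (0.13) cells. Slc7a2, the gene with the lowest ratio in pregranulosa-like cells, was also lower in surface epithelium-like (5.85 against 39.1 CPM, −2.74) and stroma-like (8.48 against 16.9 CPM) cells, and Asns, lower in pregranulosa-like cells, was higher in germ cells (65.6 against 52.1 CPM, 0.33). Cdkn1a, the cell cycle inhibitor gene p21, was higher in pregranulosa-like cells (111 against 62.0 CPM, 0.84) and surface epithelium-like cells (0.44) as well as germ cells (0.23). These genes were chosen after their values were seen, and the differences between classes were not tested.

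Some genes with large ratios lie within 20 Mb of one another (GRCm38). On chromosome 17, Glo1 starts at 30584936, H2-Ab1 at 34257689 and Pou5f1 at 35506018, and on chromosome 15, Ly6e starts at 74955051, Adck5 at 76576358, Poldip3 at 83125976 and Cyb5r3 at 83153494. The labels give a mixed strain for both pools. The grouping was not compared with chance, and whether strain haplotypes differ between the pools at these places was not tested.

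Pluripotency transcripts were higher in Tex14 -/- germ cells (0.48). The UMIs of Pou5f1 alone do not account for the sum, as the other members kept a ratio of 0.46. Leaving them out cannot decide on a reporter gate or a variant near Pou5f1 that acts on other members too. The difference of Pou5f1 itself stays open to both. Free germ cell RNA as the whole cause is argued against, since the CPM difference was 0.061 of that in germ cells in pregranulosa-like, 0.0157 in surface epithelium-like and 0.103 in stroma-like cells, though a small part of the difference may come from it. Counting noise in the meiotic level is argued against, since the matched-bin ratio at 6000 UMIs per cell was 1.10 times that at 1500 UMIs. Unthinned counts gave 0.12, but unthinned shares of UMIs gave 0.35. A younger Tex14 -/- pool cannot be told apart from the genotype, as pregranulosa markers were level (median 0.046) but need not track a small difference in age, and the Oct4-GFP gate was not tested. As a hypothesis, loss of bridges may delay the shutdown of pluripotency genes, with these alternatives open. Replicate stage-matched ovaries collected without the Oct4-GFP gate would test it.

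Of 4059 genes measured in all 4 classes, 8 differed by 1.5-fold or more in the same direction in each (Hba-a1, Hba-a2, Hbb-bs, Hbb-bt, Gm10260, Gm10076 and Gm26917 higher, Rpl27 lower). Free haemoglobin RNA is a candidate source of the haemoglobin genes, as the summed erythroid ratios of the classes lay within 0.146 of each other. Ribosomal protein genes and unnamed gene models were 19.5 times as frequent among the 8 (4 genes) as among all measured genes (2.56%). These gene groups were set after the 8 genes had been seen, so the value decides nothing, and reads shared between copies cannot be told apart from other causes. Variants linked to Tex14 cannot be told apart from chance, because Rpl27 alone lies within 20 Mb of Tex14 (12.5% against 4.34% of all genes, 2.88 times). A biological origin was not excluded for Rpl27.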
